A study of Mus musculus with 8 samples.

How the data were processed

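RNA sequencing was done on epidermal progenitors of C57BL/6 mouse embryos at embryonic day 18.5. Per the labels' protocols, cells were isolated by fluorescence-activated sorting directly into a lysis reagent and total RNA was extracted with a column kit. The 8 libraries form 4 groups of 2: wild-type control, the oncogenic allele HrasG12V, HrasG12V depleted of Mllt6, and HrasG12V depleted of Ctnnb1. The depletions were made by RNA interference, per the series title. Nothing in the labels says that the 2 libraries of a group came from separate animals, so the p-values measure only the spread between these samples. Xist was at most 0.0381 FPKM in 1 library and at least 27.2 FPKM in the other of 3 groups, so the libraries of these groups did not come from the same RNA. The sorting markers and the number of embryos per sample are not given in the sources used here.

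The authors deposited 1 table per library with an FPKM value (fragments scaled to transcript length and to the mapped fragments of the library) for each of 21954 loci and the gene name of each locus. Per the submitters' processing notes, TopHat and Cufflinks were used with the mm9 build; their versions and settings are not given in the sources used here. No read counts were used here, so the depth of each library is unknown and no counting interval is given. The FPKM of all loci summed to between 486605 and 672844 per library. In the low values, 1 fragment in the first control library was worth between 0.946 and 1.26 times as much as in the other libraries. Only 39.5% to 60.1% of the loci compared lay on such steps within 0.05%, so whole reads were not recovered. Both control libraries held the same nonzero value at 354 gene names, against at most 25 in any other pair of libraries, so those values share 1 scale. The reference annotation at hand is of another build than mm9, so genes are named as in the files and no coordinates are given.

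Of the 21954 loci, 170 name more than 1 gene. Values of rows with 1 symbol were summed (169 names lay on more than 1 locus), which left 21670 names. In some libraries 5 genes hold no value, and these were left out of all tests. Krt5 and Krt14 have none in any library, Eef1a1 has none in the control and Ctnnb1-depleted libraries, and Krt1 and Krt10 have none in the Mllt6-depleted libraries. Small RNA loci, at 660 of the loci, took 10.9% to 17.4% of the summed FPKM.

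Genes with at least 1 FPKM in at least 2 of the 8 libraries were tested, 11470 in all. limma 3.58.1 in R 4.3.3 was run on log2(FPKM + 1), with all 8 libraries in 1 fit (4 residual degrees of freedom), an intensity trend and Benjamini-Hochberg adjustment per comparison at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The comparisons were HrasG12V against control, each depletion against HrasG12V, the depletions against each other, and each depletion against control, 6 in all. The limma function camera, with a preset correlation between genes of 0.01, tested gene lists fixed before the data were examined, with Benjamini-Hochberg adjustment over the lists in each comparison. Of 38 lists, the 32 with at least 3 measured members were tested. Of their 632 symbols, 4 were matched under another name and 17 were not matched. The lists cover keratinocyte layers, signalling pathways, the cell cycle, metabolism, stress, technical signals and markers of other cell types. A further 4 lists were added after seeing the data and are reported only among the observations.

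The genes named follow a rule fixed before the data were examined. It takes the 3 targeted genes and, per main comparison, the 8 largest rises and 8 largest falls past the threshold. Both libraries of 1 group had to lie outside the range of the other, and the higher group had to average at least 3 FPKM. Symbols of unnamed gene models (Rik, Gm, LOC) and those starting with Mir or Snor were left out, so short RNA genes under other symbols, such as Rnu73b, were kept. The rule adds the 3 members of each described list with the smallest p, and the 4 largest rises and falls between the depletions, and the text prints a part of these in that order. Named outside this rule, after their values were seen, are Lor, Cdsn, Klk7, Tpt1p and Xist, Ccnd1 in HrasG12V, Etv5 with Ctnnb1 depleted, Nqo1 and Aqp9 for Ctnnb1 depletion against control, and the genes of the lists added later. Values of a gene named for 1 comparison are also given in others.

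Both comparisons with a depletion share the HrasG12V libraries with the oncogene comparison. Their relation was set beside 100 simulations of groups without an effect, drawn around the observed means with the fitted spread. The 2 shared libraries cannot be split into parts of at least 2. The tests were checked on simulated data of 11470 genes, 200 of them changed. Of genes changed 2-fold, 95% were recovered for HrasG12V against control, 91% for the Mllt6 depletion and 92% for the Ctnnb1 depletion, with false calls at 4.4%, 4% and 6.8% of all calls. In the simulated list test for the Mllt6 depletion, 3 of 3 shifted lists and 0 of 20 unshifted lists were called. These simulations draw genes independently, so they do not test the effect of correlated genes on camera.

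The 21 alternative settings comprised 8 fits that each left out 1 library and 13 others. These changed the pseudocount (0.1), the filter (none, or a mean of at least 5 FPKM), the scaling (quantile normalization, or a common 75th percentile), the libraries in the fit, a replicate block, the intensity trend, the handling of repeated symbols and the list test (camera with an estimated correlation, or fry). The other 2, a fit without small RNA loci and a fit with a sex covariate, were chosen after seeing the data. The sex covariate is the mean log2(FPKM + 1) of Ddx3y, Eif2s3y, Kdm5d and Uty. A count was taken as moved when it changed by over 1.5 times. A share of genes with opposite sign was taken as moved when it changed by more than the standard deviation between the depleted libraries taken singly. Count-based tests were not run because the files hold FPKM.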

Results

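The series asks how growth driven by oncogenic Hras in embryonic mouse epidermis depends on 2 genes, Ctnnb1 (beta-catenin) and Mllt6 (a chromatin-associated protein). RNA was sequenced from sorted epidermal progenitors of embryonic day 18.5 in 4 groups of 2 libraries each. The groups were wild-type control, HrasG12V, HrasG12V with Mllt6 depleted and HrasG12V with Ctnnb1 depleted by RNA interference. The deposited values are FPKM, fragment numbers scaled to transcript length and to the mapped fragments of a library. The depth of the libraries is not given, so no counting limit can be set on low values. Changes are differences of group means of log2(FPKM + 1), tested with limma and Benjamini-Hochberg adjustment over 11470 genes. Nothing in the labels says that the 2 libraries of a group are separate animals, so the p-values measure only the spread between these samples.

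The first question is whether the targeted transcripts changed. Ctnnb1 was lower in its depletion, at 206.7 ± 1.13 FPKM (SD, n = 2) against 320.5 ± 13.1 in HrasG12V. This was 0.646 times the HrasG12V level (log2 -0.63, SE 0.123, limma adjusted p = 0.0038). Mllt6 was measured at 4.07 ± 0.0355 FPKM in its depletion and 7.15 ± 0.267 in HrasG12V, with both depleted libraries below both HrasG12V libraries. That difference did not pass the threshold (0.622 times, log2 -0.69, limma adjusted p = 0.0619). It passed after quantile normalization, with only the 2 groups compared, without small RNA loci and without either control library. With a sex covariate, which nearly coincides with the Mllt6-depleted group, the estimate lay near no change and its sign reversed. In HrasG12V, Mllt6 was higher than in control (5.29 ± 1.3 FPKM; log2 0.39, limma adjusted p = 0.0498), a call that ended in 7 of the 8 fits that each left out 1 library and held only in the fit without control replicate 1. The adjusted p was between 0.0689 and 0.234 in these 7 fits, and the highest came without control replicate 2 (log2 0.18). Against the Ctnnb1 depletion, Mllt6 was lower in the Mllt6 depletion by a difference that passed (log2 -0.67, limma adjusted p = 0.006). Hras, listed as Hras1, was at 111.5 ± 21.1 FPKM in HrasG12V and 94.96 ± 13.5 in control and did not change detectably (log2 0.22, limma adjusted p = 0.3). It was lower with Ctnnb1 depleted, at 77.1 ± 2.51 FPKM (log2 -0.51 against HrasG12V, limma adjusted p = 0.0336). The HrasG12V libraries lay at 126.4 and 96.6 FPKM, the latter between the control libraries (85.43 and 104.5). Whether this call holds when 1 library is left out was not examined. The files do not separate the mutant allele from the wild-type one.

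**Figure D1:**
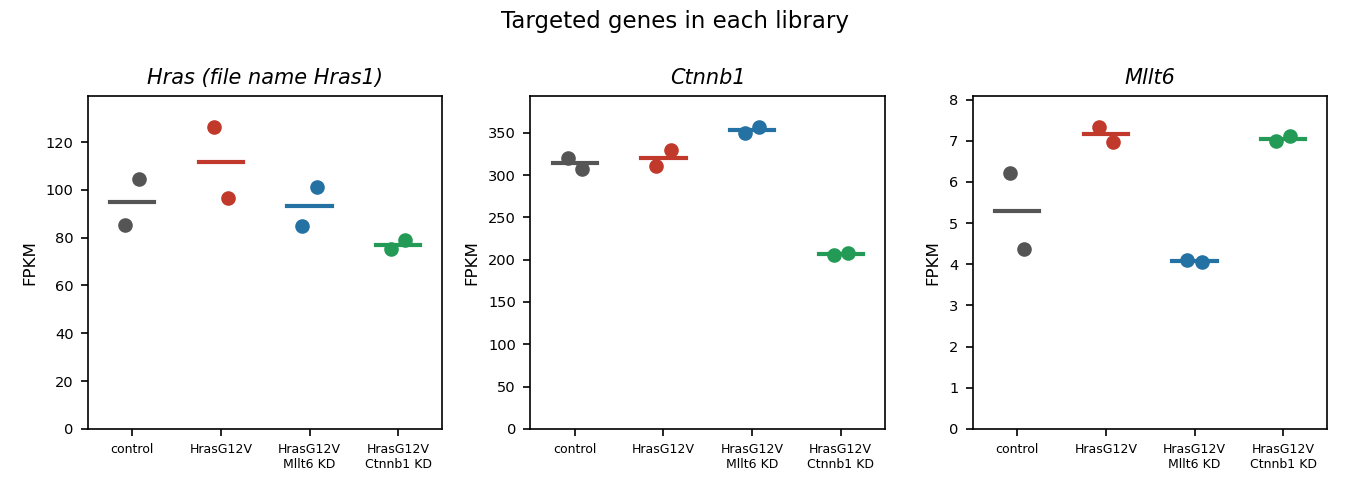
FPKM of Hras, Ctnnb1 and Mllt6 in each of the 8 libraries (points) with the group mean (bars), on linear axes that start at 0. Ctnnb1 averaged 206.7 FPKM in its depletion against 320.5 in HrasG12V, and Mllt6 averaged 4.07 in its depletion against 7.15.

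HrasG12V against control asks what differed in cells that carry the oncogene. About as many genes passed the threshold as did not, with many cell cycle, histone, Hox and Wnt target genes higher and many matrix, cytokine and basal keratinocyte genes lower. These lists were called by camera, none of them with an estimated correlation (adjusted p = 0.458 to 0.755). Of 11470 genes, 5817 changed, 3576 higher and 2241 lower, and 1484 of them by at least 2-fold. The median change of all genes was 0.11.

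Among the largest rises, Fos went from 108 ± 14 to 1049 ± 34.7 FPKM (9.67-fold, log2 3.27). The water channel gene Aqp9 (log2 4.04), the oxidoreductase gene Nqo1 (3.63), the secreted glycoprotein gene Stc2 (3.58) and the histone gene Hist2h2bb (3.20) rose as well. Fos belongs to a list of 19 early response genes that was fixed as a sign of cell handling, of which 7 rose, with Egr1 at 2.25 and Dusp1 at 1.63, and 2, Klf6 and Atf3, fell, also when adjusted over the list alone (not called, camera adjusted p = 0.27). The short RNA genes Rnu12 and Scarna8 were listed at 0 in both control libraries and averaged 31.3 ± 12.4 and 16.6 ± 12.3 FPKM in HrasG12V. The largest falls included Serpinb2, from 549.9 ± 117 to 13.4 ± 7.54 FPKM (log2 -5.35), and Tnfrsf12a, from 730 ± 65.8 to 53.9 ± 4.86 FPKM (log2 -3.74). Fhl2 (log2 -4.51), the integrin gene Itgb6 (-4.31), the urokinase receptor gene Plaur (-4.31), Tnfsf18 (-4.21) and Nppb (-3.75) fell too.

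Proliferation genes rose. Of 22 G2 and mitosis genes, 16 rose (18 adjusted over the list alone), among them Plk1 (log2 2.67), Bub1b (1.21) and Aurkb (1.13), and the list was called by camera (adjusted p = 3.55e-05; adjusted p = 0.755 with an estimated correlation). Of 23 DNA replication genes, 13 rose (16 adjusted over the list alone), such as Mcm2 (1.21) and Mcm3 (1.08), with camera adjusted p = 0.00289 (adjusted p = 0.755 with an estimated correlation). All 10 changed genes of 12 replication-dependent histone genes rose, 10 also when adjusted over the list alone, with Hist1h3a at 2.13 and Hist1h3c at 2.05 (camera adjusted p = 3.55e-05, and 0.458 with an estimated correlation). This histone list was fixed as a technical signal, for transcripts without a poly(A) tail, and not as a proliferation list. Of 21 ribosome biogenesis genes, 16 rose and 1 fell (16 and 2 adjusted over the list alone), including Cad (1.36) and Polr1b (1.24), with camera adjusted p = 0.00994 (adjusted p = 0.755 with an estimated correlation).

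Wnt and developmental genes rose in part. Of 14 Wnt targets, 10 rose and 1 fell, the same counts as adjusted over the list alone, with Axin2 going from 2.37 ± 0.0835 to 15.5 ± 0.258 FPKM (log2 2.29), Apcdd1 at 1.46 and Rnf43 at 1.11 (camera adjusted p = 0.0153; adjusted p = 0.755 with an estimated correlation). Ccnd1, named after its values were seen, was the member that fell (log2 -0.92). Of 11 Hox and Meis genes, 10 rose, 10 also when adjusted over the list alone, led by Hoxa2 (2.28), Hoxc4 (1.88) and Hoxa5 (1.48), with camera adjusted p = 0.00114 (adjusted p = 0.755 with an estimated correlation).

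Matrix remodelling, cytokine and basal keratinocyte genes fell. Of 15 matrix remodelling genes, 12 fell, 12 also when adjusted over the list alone, among them Itga5 (log2 -2.49) and Snai2 (-2.01), with camera adjusted p = 6.09e-06 (adjusted p = 0.755 with an estimated correlation). Of 19 cytokines and chemokines, 11 fell and 1 rose, also when adjusted over the list alone, with Cxcl16 at -2.43, Il33 at -2.02 and Il24 at -1.99 (camera adjusted p = 0.0027; adjusted p = 0.755 with an estimated correlation). Of 14 basal keratinocyte genes, 8 fell, including Igfbp3 (-3.08) and Itgb1 (-1.39), and 1, Bcl11b, rose (2.09), the same counts as adjusted over the list alone (camera adjusted p = 0.00296; adjusted p = 0.755 with an estimated correlation). The cholesterol synthesis list was called lower, with 9 genes lower and 5 higher of 19, also when adjusted over the list alone (Cyp51 -1.65, Dhcr7 1.16; camera adjusted p = 0.0439; adjusted p = 0.774 with an estimated correlation), and not without control replicate 2 (adjusted p = 0.0988) or HrasG12V replicate 2 (0.116). Markers of other cell types moved singly: Dcn (-1.38) and Postn (-1.04) fell and Col5a1 (0.63; limma adjusted p = 0.0661 without HrasG12V replicate 2) rose among 6 fibroblast markers, and Trpm1 (-1.94), Cd74 (-1.70) and Acta1 (-1.16) fell among 3 melanocyte, 3 immune and 3 muscle markers. Camera called none of these 4 lists, and fry called the fibroblast and melanocyte lists lower (adjusted p = 0.0343 and 0.0269).

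Late differentiation genes rose in part, and ERK targets went both ways. Of 22 granular and cornified layer genes, 11 rose, also when adjusted over the list alone, such as Ivl, from 2.75 ± 1.01 to 20.2 ± 1.04 FPKM (log2 2.52), Asprv1 (1.13) and Casp14 (1.08), with camera adjusted p = 0.0439 (adjusted p = 0.839 with an estimated correlation). This list was not called without control replicate 2 (adjusted p = 0.431) or HrasG12V replicate 2 (0.19). Krt1 and Krt10, which have no value in the Mllt6 depletion and were not tested, averaged 1.88 and 1.68 times their control level. Of 23 ERK feedback and target genes, 5 rose, including Etv4 (2.79), Spry2 (2.53) and Etv5 (1.94), and 11 fell, the same counts as adjusted over the list alone, and camera did not call the list.

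Mllt6 depletion against HrasG12V asks what the depletion changed in cells that carry the oncogene. Few genes passed, and among the lists fixed beforehand the one with most changed genes was that of granular and cornified layer genes, which were lower. Of 11470 genes, 182 changed, 84 higher and 98 lower, 108 of them by at least 2-fold, and 1556 had an unadjusted p under 0.05. The 182 became 102 without a filter, 63 at a mean of at least 5 FPKM and 97 with a replicate block. With a sex covariate, which nearly coincides with the Mllt6-depleted group so that few genes can pass, 3 genes changed. The count rested on single libraries, with 44 without HrasG12V replicate 1, 34 without HrasG12V replicate 2, 300 without Mllt6-depleted replicate 1, 102 without Mllt6-depleted replicate 2, 107 without Ctnnb1-depleted replicate 1 and 105 without Ctnnb1-depleted replicate 2. Of the changed genes, 46.2% were higher, and 57.3% with a common 75th percentile (199 genes, 114 higher and 85 lower). The share was 29.6% of 125 genes with only the 2 groups compared, and 70% of the 300 genes without Mllt6-depleted replicate 1, so neither direction prevailed in all settings.

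The largest rise was that of the short RNA gene Rnu73b, from 0.317 ± 0.448 to 180.3 ± 12.1 FPKM. Rnu73b averaged 216.6 ± 0 FPKM in control, the same value in both libraries, and 470.8 ± 207 with Ctnnb1 depleted. Only the HrasG12V libraries were thus near 0. How many fragments lay on this short locus is unknown, so its changes may rest on few fragments. Among genes that the rule names, it also had the largest fall in HrasG12V against control (log2 -7.41) and the largest rise with Ctnnb1 depleted (8.455). Krt79 went from 8.5 ± 0.752 to 37.3 ± 13.8 FPKM (3.9-fold, log2 1.96), Krt80 from 12.03 ± 2.65 to 36.5 ± 2.5 (log2 1.54) and Ly6a from 2.99 ± 0.652 to 13.7 ± 4.93 (log2 1.85). Cyp4b1 (1.67), Dapl1 (1.51), Tppp3 (1.46) and Mgp (1.41) rose too. Without HrasG12V replicate 1 or 2, Krt79 no longer passed (log2 2.04 and 1.88, limma adjusted p = 0.0657 and 0.0923). Without HrasG12V replicate 2, neither did Krt80 (log2 1.33), Dapl1 (1.29) or Ly6a (1.68), and Cyp4b1, Tppp3 and Mgp lost their call in 6, 6 and 7 of the 8 fits that each left out 1 library.

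Cornified envelope genes fell. Of 22 granular and cornified layer genes, 10 fell (17 adjusted over the list alone), and the list median was -1.44 (camera adjusted p = 1.68e-15; adjusted p = 0.406 with an estimated correlation). Lce1h went from 29.6 ± 2.55 to 3.46 ± 1.63 FPKM (log2 -2.82) and Lce1a1 from 91.9 ± 12.1 to 13.6 ± 7.92 (log2 -2.78). Lor (log2 -2.52), Cdsn (-2.04) and Klk7 (-1.54), members of the list named after their values were seen, fell as well. These calls were close to the threshold: Lce1a1, Lce1d and Lce1f (log2 -2.76 and -2.78 for the latter) lost theirs in 5 of the 8 fits that each left out 1 library, with HrasG12V replicate 1 or 2, Mllt6-depleted replicate 2, or either Ctnnb1-depleted library left out, and Lce1h in 3 of 8. The lowest and highest change in these fits were -3.36 and -2.20 for Lce1a1, -3.33 and -2.19 for Lce1d, -3.43 and -2.13 for Lce1f, and -3.21 and -2.44 for Lce1h. In no fit did the sign change. The largest fall of a protein-coding gene was Tpt1, from 302.9 ± 54.2 to 16.4 ± 0.231 FPKM (log2 -4.11). The similarly named locus Tpt1p, chosen after its values were seen, was at 4250 ± 628 FPKM in HrasG12V and 3468 ± 522 with Mllt6 depleted and did not change detectably (log2 -0.29). How reads were divided between both loci was not tested.

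Y-linked genes were near 0 in both Mllt6-depleted libraries. Eif2s3y was listed at 0 in both and averaged 14.8 ± 6.18 FPKM in HrasG12V. Ddx3y was at 0.0251 ± 0.00521 against 8.38 ± 3.31 FPKM (log2 -3.15), a call that ended without HrasG12V replicate 1 (log2 -2.78, limma adjusted p = 0.0536). In all, 4 of the 5 sex-linked genes were lower, also when adjusted over the list alone (camera adjusted p = 1.04e-05; adjusted p = 0.336 with an estimated correlation). Xist, the fifth, was at 57.4 ± 1.61 FPKM in the Mllt6 depletion and varied between libraries in HrasG12V (13.6 ± 19.2), control (22.1 ± 31.2) and the Ctnnb1 depletion (15.9 ± 22.4).

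Ribosomal protein and replication genes shifted by small amounts that few members passed singly. The median of 32 ribosomal protein genes was -0.50, with 0 past the limma threshold and 22 at an unadjusted p under 0.05 (camera adjusted p = 1.82e-11; adjusted p = 0.496 with an estimated correlation). The median of 23 DNA replication genes was -0.31, with 0 past the limma threshold, 5 lower adjusted over the list alone and 11 at an unadjusted p under 0.05 (camera adjusted p = 5.31e-07; adjusted p = 0.406 with an estimated correlation). Of 12 replication-dependent histone genes, the list fixed as a technical signal, 2 fell (5 adjusted over the list alone), Hist1h3a (log2 -0.85) and Hist1h2ab (-0.60). Its camera adjusted p was 0.000106 (adjusted p = 0.336 with an estimated correlation). Both histone calls ended without either HrasG12V library or either Mllt6-depleted library. In those fits Hist1h3a lay between -0.99 and -0.71 and Hist1h2ab between -0.65 and -0.54. The call of Hist1h2ab also ended without either Ctnnb1-depleted library (log2 -0.595 in both fits). The median of 22 G2 and mitosis genes was -0.22, with 0 past the limma threshold and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.000587; adjusted p = 0.538 with an estimated correlation).

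The cholesterol synthesis, hair follicle, fibroblast and immune lists shifted upward, while camera did not call melanocyte markers (adjusted p = 0.114) or muscle markers (adjusted p = 0.267; median -0.26). The median of 19 cholesterol synthesis genes was 0.32, with 0 past the limma threshold and 8 at an unadjusted p under 0.05 (camera adjusted p = 3.54e-06; adjusted p = 0.406 with an estimated correlation). Of 16 hair follicle genes, 1, Krt79, rose (2 adjusted over the list alone), with camera adjusted p = 0.000258 (adjusted p = 0.496 with an estimated correlation). Of 6 fibroblast markers, 1, Postn, rose (log2 1.06; 2 adjusted over the list alone), with camera adjusted p = 0.0204 (adjusted p = 0.363 with an estimated correlation). The cholesterol list was not called without Mllt6-depleted replicate 1 (camera adjusted p = 0.0622), the hair follicle list without Mllt6-depleted replicate 2 (0.0789), and the fibroblast list without HrasG12V replicate 1 (0.0593) or Mllt6-depleted replicate 1 (0.0622). The call of Postn ended in 5 of the 8 fits that each left out 1 library, with log2 changes of 0.83 to 1.28. Of 3 immune markers, 0 passed the limma threshold over all genes and 3 rose adjusted over the list alone, Cd74 (1.11), C1qb (0.65) and Cd52 (0.57), with camera adjusted p = 0.00587 (adjusted p = 0.336 with an estimated correlation). For 14 Wnt targets and 23 ERK targets, 0 genes passed the limma threshold, with 4 and 3 at an unadjusted p under 0.05, and camera called neither list.

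Ctnnb1 depletion against HrasG12V asks the same question for beta-catenin. The change was broad and for many groups ran against that of the oncogene: many matrix, cytokine and basal keratinocyte genes were higher, and many cell cycle, histone and Hox genes were lower. These lists were called by camera, none of them with an estimated correlation (adjusted p = 0.319 to 0.631). ERK target genes, which the oncogene moved both ways, were mostly higher. Of 11470 genes, 5896 changed, 2380 higher and 3516 lower, 1268 of them by at least 2-fold. The count was 3603 without HrasG12V replicate 1 and 3366 without Ctnnb1-depleted replicate 1. The median change of all genes was -0.12.

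Several genes that the oncogene lowered led the rises. Plaur went from 2.68 ± 1.72 to 137.9 ± 9.82 FPKM (log2 5.32), Serpinb2 from 13.4 ± 7.54 to 483 ± 51.9 (log2 5.18) and Fhl2 from 2.8 ± 0.42 to 97.7 ± 15.4 (log2 4.69). Ifi202b (log2 4.68), Itgb6 (4.51), Ets1 (4.02) and Nrg1 (3.96) rose as well. Among the falls, the calmodulin gene Calm3 went from 51.2 ± 8.07 to 7.09 ± 0.359 FPKM (log2 -2.68), below its control level of 21.6 ± 1.06. Ivl (-2.58), Aqp9 (-2.34), Aldh1l2 (-2.05), Plk1 (-2.04) and Adm2 (-2.03) fell, as did Hist2h2bb (-2.61).

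Matrix, cytokine and ERK target genes rose. Of 15 matrix remodelling genes, 12 rose (13 adjusted over the list alone), with Itga5 at 3.29 and Mmp9 at 1.78 (camera adjusted p = 1.43e-07; adjusted p = 0.631 with an estimated correlation). Of 23 ERK feedback and target genes, 18 rose and 3 fell (18 and 4 adjusted over the list alone), among them Epha2 (2.87) and Dusp6, from 74.4 ± 9.3 to 265.5 ± 13.6 FPKM (log2 1.83), while Etv5, named after its values were seen, fell (-1.28), with camera adjusted p = 0.000129 (adjusted p = 0.631 with an estimated correlation). Of 19 cytokines and chemokines, 11 rose, also when adjusted over the list alone, such as Il24 (3.27), Cxcl16 (2.72) and Csf1 (1.55), with camera adjusted p = 0.00013 (adjusted p = 0.631 with an estimated correlation). Of 14 basal keratinocyte genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone), including Igfbp3 (2.41) and Itgb1 (1.65), with camera adjusted p = 0.000578 (adjusted p = 0.631 with an estimated correlation). Of the markers of other cell types, Postn (1.09), Dcn (0.81), Trpm1 (1.18), Cd74 (1.46) and Acta1 (1.54) rose and Mylpf (-0.43) fell, and camera and fry called none of their 4 lists. Cd74 did not pass without HrasG12V replicate 1 (limma adjusted p = 0.0585) or Ctnnb1-depleted replicate 1 (0.0921), nor Mylpf without HrasG12V replicate 1 (0.194) or either Ctnnb1-depleted library (0.106 and 0.103).

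Proliferation and Hox genes fell. Of 22 G2 and mitosis genes, 19 fell (20 adjusted over the list alone), with Bub1b at -1.06 and Aurkb at -0.99 (camera adjusted p = 5.35e-06; adjusted p = 0.631 with an estimated correlation). Of 23 DNA replication genes, 18 fell (20 adjusted over the list alone), such as Mcm7 (-1.10) and Uhrf1 (-0.92), with camera adjusted p = 5.09e-05 (adjusted p = 0.631 with an estimated correlation). All 12 replication-dependent histone genes, the list fixed as a technical signal, fell, also when adjusted over the list alone (camera adjusted p = 3.74e-06, and 0.319 with an estimated correlation). Of 11 Hox and Meis genes, 7 fell, also when adjusted over the list alone, led by Hoxa2 (-1.75), Hoxc4 (-1.53) and Hoxc5 (-1.18), with camera adjusted p = 0.0129 (adjusted p = 0.631 with an estimated correlation). Of 21 ribosome biogenesis genes, 13 fell, also when adjusted over the list alone, including Cad (-0.82), with camera adjusted p = 0.0329 (adjusted p = 0.701 with an estimated correlation), and 0.0514 without Ctnnb1-depleted replicate 2.

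Wnt targets fell in part. Of 14, 5 fell over all genes and 4 adjusted over the list alone, with Axin2 going from 15.5 ± 0.258 to 5.61 ± 1.46 FPKM (log2 -1.34), Wif1 at -1.07 and Apcdd1 at -0.76, and camera did not call the list (adjusted p = 0.178; not called with an estimated correlation either). Of 16 adherens junction and desmosome genes, 7 rose and 1 fell, also when adjusted over the list alone, among the rises Vcl (2.51), Cdh1 (1.45) and Dsg2 (0.98), and camera did not call the list. Of 13 genes of the Dot1l complex and its partners, 7 rose, also when adjusted over the list alone, including Aff4 (1.28), with camera adjusted p = 0.0407 (adjusted p = 0.701 with an estimated correlation), and 0.071 without HrasG12V replicate 1 or 0.0652 without Ctnnb1-depleted replicate 2. Of 22 granular and cornified layer genes, 10 fell and 1 rose (8 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0543). Krt1 and Krt10, not tested, averaged 0.534 and 0.564 times their HrasG12V level.

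How far each depletion ran against the oncogene was compared over the 5817 genes that HrasG12V changed. Of these, 95.3% had the opposite sign in the Ctnnb1 depletion and 67.9% in the Mllt6 depletion. Control and Ctnnb1-depleted libraries lay together in the main split of the 8 libraries. An unlabelled handling batch along this split cannot be told apart from the depletion in the Ctnnb1 share. With a sex covariate, which nearly coincides with the Mllt6-depleted group, 5013 genes were called in HrasG12V. Among these, the Mllt6 share was 32.2% and the Ctnnb1 share 97.5%, so the direction of the Mllt6 share depends on that term. Groups simulated without an effect, which share the HrasG12V libraries in the same way, gave 55.4% and 55.2%, so part of each share stems from the shared libraries. With the opposite direction past the threshold, there were 4292 genes in the Ctnnb1 depletion, against 1561 expected from the numbers of changed genes, and 113 in the Mllt6 depletion, against 47.0. These expected numbers do not allow for the shared HrasG12V libraries. The simulated groups gave at most 3 such genes. Hardly any gene was called for a depletion in them, so this does not measure the effect of sharing. The count of 113 was smaller without a filter, at a mean of at least 5 FPKM and with a replicate block. With the sex covariate, where few genes can pass for the Mllt6 depletion, 1 gene was left of this kind. The genes that HrasG12V raised had a median change of 0.67, then -0.56 with Ctnnb1 depleted and -0.09 with Mllt6 depleted. Plk1, at 3.61 ± 0.856 FPKM in control and 28.2 ± 3.98 in HrasG12V, was at 6.08 ± 0.707 with Ctnnb1 depleted and 18.5 ± 1.88 with Mllt6 depleted. Serpinb2 was at 17.5 ± 1.66 FPKM with Mllt6 depleted, close to its HrasG12V level. The 4292 genes became 2635 without HrasG12V replicate 1 and 2773 without Ctnnb1-depleted replicate 1. The 113 genes became 31 and 25 without HrasG12V replicates 1 and 2, 204 and 61 without Mllt6-depleted replicates 1 and 2, and 71 and 67 without Ctnnb1-depleted replicates 1 and 2.

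**Figure D2:**
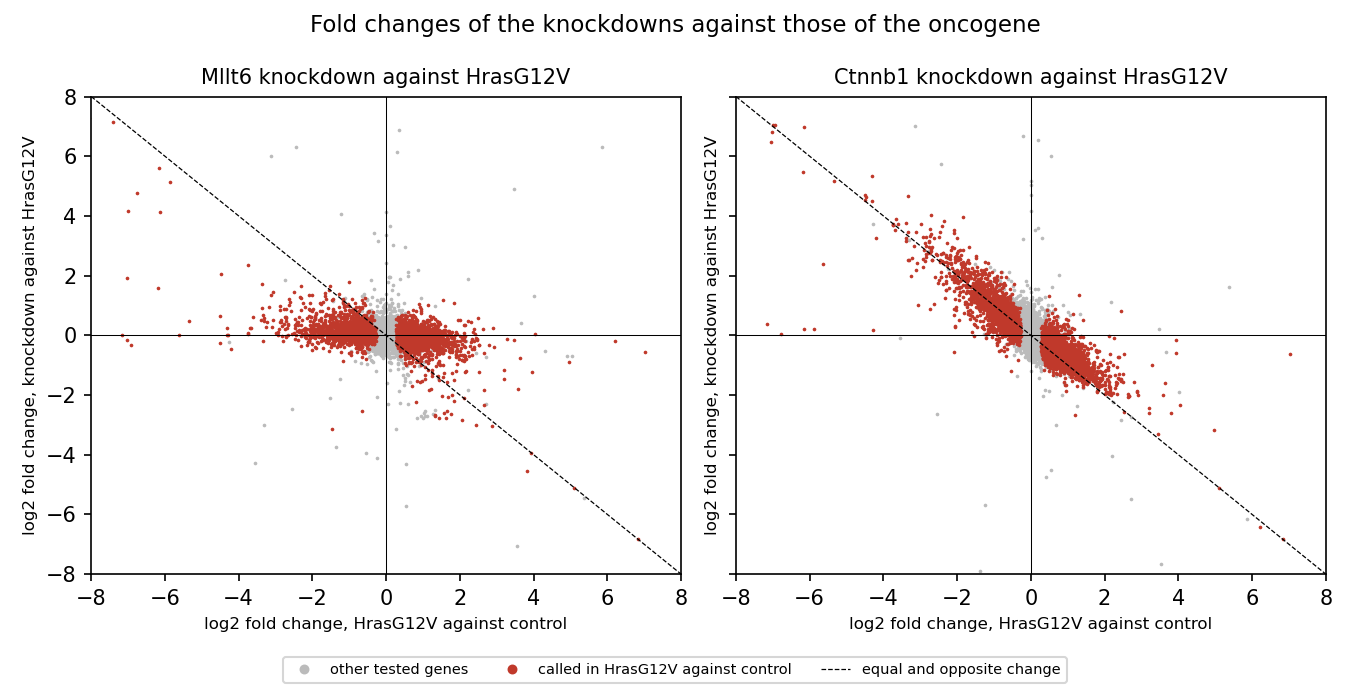
Change of each gene in a depletion against HrasG12V (vertical, log2) over its change in HrasG12V against control (horizontal, log2), for Mllt6 (left) and Ctnnb1 (right), with genes changed by HrasG12V in red and 8 of 11470 genes outside the axes. Of the red genes, 95.3% lie on opposite sides of 0 for Ctnnb1 and 67.9% for Mllt6. A fit with a sex covariate, not drawn, gave 32.2% for Mllt6 among the 5013 genes that this fit called in HrasG12V.

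The depletions were also compared with each other, since their changes against HrasG12V share a reference. Of 11470 genes, 5592 differed, 3189 higher and 2403 lower in the Mllt6 depletion, and 2985 without Ctnnb1-depleted replicate 1. With a sex covariate 5 genes differed, since the Mllt6-depleted libraries alone lack Y-linked reads and the covariate nearly coincides with that group. Plaur (log2 -5.32), Serpinb2 (-4.71), Tpt1 (-4.73) and Ddx3y (-4.62) were lower in the Mllt6 depletion, and Krt79 (2.85), Calm3 (2.57) and Aqp9 (2.38) were higher. Against HrasG12V, 94 genes changed in the same direction in both depletions, against 47.5 expected from the numbers of changed genes, and 12 in opposite directions, against 46.1. The 94 became 27 without HrasG12V replicate 1, 24 without HrasG12V replicate 2, 165 and 56 without Mllt6-depleted replicates 1 and 2, and 52 and 58 without Ctnnb1-depleted replicates 1 and 2. Here too the expected numbers ignore the shared libraries. The count of 94 was also smaller without a filter, at a mean of at least 5 FPKM and with a replicate block. With the sex covariate, where few genes can pass for the Mllt6 depletion, 1 gene changed in both depletions. The correlation of the changes across genes, which are not independent replicates, was 0.335. Groups simulated without an effect of either depletion gave 0.331 to 0.626. Only noise is left in them, mostly shared through the HrasG12V libraries, so this range cannot judge the observed correlation. The covariance, 0.111, lay above the highest simulated one, 0.0311. Genes were drawn independently in these simulations, so shifts of a whole HrasG12V library, which enter both changes, are not covered.

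Each depletion was set against control to show what remained different from cells without the oncogene. With Mllt6 depleted, 5569 genes differed from control, and 4636 of these had changed in the same direction in HrasG12V, against 1473 expected from the numbers of changed genes. Groups simulated without an effect gave at most 3. Hardly any gene was called in these groups, so this does not measure the effect of sharing. The expected numbers here ignore the shared control libraries. With a sex covariate, which nearly coincides with the Mllt6-depleted group, 8 genes differed from control. Of the 5817 genes that HrasG12V changed, 98.0% had the same sign, against 55.3% in the simulated groups, which share the control libraries. With Ctnnb1 depleted, 986 genes differed, 634 higher and 352 lower. There were 455 without a filter, 481 at a mean of at least 5 FPKM, 441 with a replicate block, 516 with only the 2 groups compared and 612 with the sex covariate. This count was 1958 without control replicate 1, 159 without control replicate 2, 169 without Ctnnb1-depleted replicate 1 and 78 without Ctnnb1-depleted replicate 2. The share of higher genes was 64.3%, and 51.4% of 1106 genes after quantile normalization. In the same direction as in HrasG12V, 571 genes remained changed, against 266.4 expected (996 without control replicate 1, 104 without control replicate 2, 349 without HrasG12V replicate 2, 136 without Ctnnb1-depleted replicate 1 and 43 without Ctnnb1-depleted replicate 2), and 79 had changed in the opposite direction. The 571 became 245 without a filter, 286 at a mean of at least 5 FPKM and 296 with only the 2 groups compared. Of the 5817 genes, 66.9% had the same sign, against 55.4% in such simulated groups. Fos was 2.26 above control (log2), against 3.27 in HrasG12V, and Egr1 was 2.16 against 2.25. Both belong to 19 early response genes, a list fixed as a sign of cell handling, of which 4 were higher (11 adjusted over the list alone; camera adjusted p = 0.000181; adjusted p = 0.818 with an estimated correlation). Spry2 was at 20.3 ± 2.89 FPKM, against 4.67 ± 0.11 in control and 31.6 ± 0.643 in HrasG12V. Nqo1 (log2 2.05) and Aqp9 (1.70) also stayed above control. Of 23 ERK feedback and target genes, 10 were higher (16 adjusted over the list alone), with Dusp6 at 1.70 and Tgfa at 1.32 (camera adjusted p = 2.02e-07; adjusted p = 0.721 with an estimated correlation). Of 14 Wnt targets, 5 were higher and 1 was lower (9 and 1 adjusted over the list alone), Axin2 higher (0.95) and Ccnd1 lower (-1.19), with camera adjusted p = 0.00335 (adjusted p = 0.721 with an estimated correlation). Of 22 G2 and mitosis genes, 0 passed the limma threshold against control, with 2 at an unadjusted p under 0.05.

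**Figure D3:**
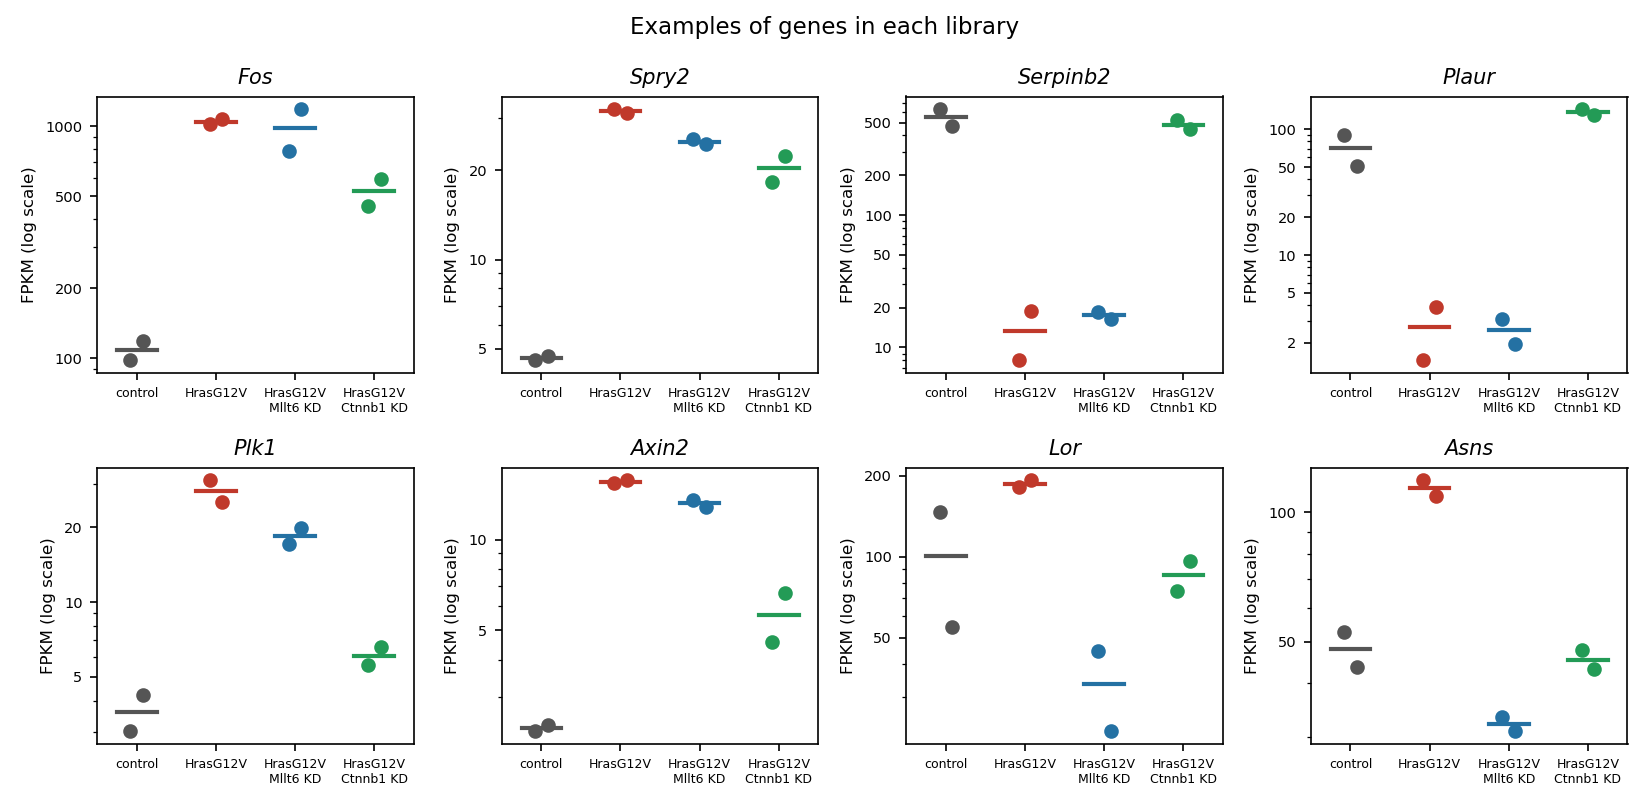
FPKM on log axes of 8 genes in each library (points) with the group means (bars). With Ctnnb1 depleted, Serpinb2 lies near control, Plaur lies above control, and Plk1, Fos and Spry2 lie between control and HrasG12V, Plk1 nearer to control. Lor and Asns are lowest with Mllt6 depleted.

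Camera with a correlation estimated from the data called none of the lists that it called with the preset correlation, 11 in HrasG12V against control, 15 in the Mllt6 depletion and 12 in the Ctnnb1 depletion. At an unadjusted p under 0.05, the estimated correlation left 1, 4 and 1 lists of the 32 tested, and fry, which tests each list against no change, called 13, 4 and 12.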

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

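The fit without small RNA loci and the fit with a sex covariate were chosen after the results were seen. In no fit that left out 1 library did a gene that the rule names in the 3 main comparisons, or a list called there, pass the threshold in the opposite direction. Fits that left out 1 library gave 4101 to 5605 changed genes for HrasG12V against control, 34 to 300 for Mllt6 depletion, 3366 to 6306 for Ctnnb1 depletion, 2985 to 6037 between the depletions, and 3992 to 5483 and 78 to 1958 for the Mllt6 and Ctnnb1 depletions against control. They gave 25 to 204 genes changed oppositely by Mllt6 depletion and 2635 to 4360 by Ctnnb1 depletion, with opposite signs at 62.7% to 78.5% and 92.2% to 97.6%, and 24 to 165 genes changed alike in both. Called lists ran from 9 to 12, 11 to 18 and 10 to 14. In these fits Mllt6 ranged from 0.18 to 0.60 in HrasG12V against control and from -0.72 to -0.65 with Mllt6 depleted, Ctnnb1 from -0.67 to -0.59 with Ctnnb1 depleted, and Hras1 from 0.03 to 0.42 in HrasG12V. A group left with 1 library was assumed to vary like the others.

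For Mllt6 depletion against HrasG12V, the Ctnnb1 depletion against control, the opposite changes with Mllt6 depleted and the changes alike in both, counts were 102, 455, 60 and 55 without a filter, 63, 481, 44 and 38 at a mean of at least 5 FPKM and 97, 441, 62 and 56 with a replicate block. The replicate numbers did not pair the libraries (correlations of -0.106 to 0.004). With the block, 283 genes of the Ctnnb1 depletion kept the change of HrasG12V against control. With only the 2 groups compared, the count for Ctnnb1 depletion against control was 516. Without small RNA loci Mllt6 depletion changed 259 genes. The increase of Mllt6 in HrasG12V did not pass with a pseudocount of 0.1 (0.45), quantile normalization (0.26) or a common 75th percentile (0.35), nor at 0.39 without a filter, at a mean of at least 5 FPKM, with 2 groups, with the block or without the trend. Its fall with Mllt6 depleted passed after quantile normalization (-0.73), with 2 groups and without small RNA loci (-0.69 in both). The cause was not tested.

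The sex covariate is nearly the same as the Mllt6-depleted group, and the standard error of that group's change was 3.29 times as large, so few genes can pass. With it, 3 genes changed with Mllt6 depleted (limma), 5 between the depletions, 8 for Mllt6 depletion and 612 for Ctnnb1 depletion against control, 8 lists were called with Mllt6 depleted, 1 gene changed oppositely and 1 in both, and opposite signs were at 32.2% for Mllt6 and 97.5% for Ctnnb1. The changes of Mllt6 (0.024) and Mgp (-0.21) with Mllt6 depleted reversed. Uty (0.41) reversed too, but it is among the genes averaged in the covariate, so its sign there is no result. Ribosomal proteins reversed with Ctnnb1 depleted after quantile normalization, to a median of -0.029 from 0.23 (camera). Camera with an estimated correlation called 0 lists in HrasG12V, 0 with Mllt6 depleted and 0 with Ctnnb1 depleted, and fry called 4 with Mllt6 depleted. The depth is unknown, so what low values can show is not set. Count-based tests were not run.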

Other observations

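Of the tests in this part, the comparison of the other called genes between libraries that differ in sex-linked reads was set before its result was seen, and the 6 others and the 4 added gene lists were chosen after the results were seen.

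Reading the changed genes brought up groups that no list fixed beforehand covered, and 4 lists were then tested, with Benjamini-Hochberg adjustment over the 4. Genes of the amino acid response fell with Mllt6 depleted, 12 of 22 (17 adjusted over the list alone), with Asns going from 114 ± 6.57 to 32.2 ± 1.78 FPKM (log2 -1.79), Chac1 at -2.54 and Mthfd2 at -2.24 (camera adjusted p = 5.2e-20; p = 0.00221 with an estimated correlation). HrasG12V had raised 16 of these genes and lowered 3 (camera adjusted p = 0.000175; p = 0.0457 with an estimated correlation), and with Ctnnb1 depleted 16 fell and 1 rose (camera adjusted p = 0.000166; p = 0.0453 with an estimated correlation). Transfer RNA synthetase genes went the same way, with 13 of 18 higher in HrasG12V (14 adjusted over the list alone), 6 lower with Mllt6 depleted (11 adjusted over the list alone; camera adjusted p = 9.36e-12, and p = 0.0202 with an estimated correlation), and 14 lower and 1 higher with Ctnnb1 depleted (15 and 1 adjusted over the list alone). With an estimated correlation, this list had p = 0.0988 in HrasG12V and p = 0.0873 with Ctnnb1 depleted. Of 15 Nrf2 targets, 7 rose and 2 fell in HrasG12V, 3 fell with Mllt6 depleted (5 adjusted over the list alone), and 6 fell and 2 rose with Ctnnb1 depleted. With an estimated correlation, these targets had p = 0.122, 0.0157 and 0.32 in that order. Of 20 actin cytoskeleton genes targeted by Srf, 19 fell in HrasG12V, with Tagln at -3.65, Myl9 at -3.30 and Actb at -1.16 (camera adjusted p = 4.84e-12; p = 0.103 with an estimated correlation). All 20 rose with Ctnnb1 depleted (Tagln 3.90, Tpm1 2.98, Actb 1.74; camera adjusted p = 1.07e-12; p = 0.0963 with an estimated correlation), and 0 passed the limma threshold with Mllt6 depleted, where the median was 0.16 (camera adjusted p = 0.022; p = 0.535 with an estimated correlation). These lists were picked on the same libraries, so their tests are no independent evidence. The transcript Gt(ROSA)26Sor was at 22.2 ± 2.76 FPKM in control and at 4.63 ± 0.937 in HrasG12V, 4.87 ± 1.05 with Mllt6 depleted and 5.78 ± 1.31 with Ctnnb1 depleted. Control thus differed in this transcript from all groups with the oncogene, the Ctnnb1 depletion included. Whether control differs from these groups in more than the oncogene was not tested.

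The Ctnnb1-depleted libraries resembled control, with correlations across genes of 0.951 to 0.967 with the control libraries and 0.892 to 0.924 with the HrasG12V libraries. The shared HrasG12V libraries are argued against as the whole source. The covariance of the changes by HrasG12V and by the depletion was -0.4928, and the lowest in 100 simulations without an effect was -0.0397. These simulations too drew genes independently, so shifts of a whole HrasG12V library are not covered. Control libraries under the Ctnnb1-depleted label are argued against by Ctnnb1, at 205.9 and 207.5 FPKM in these libraries and 320.3 and 307.2 in control. Gt(ROSA)26Sor was at 5.78 ± 1.31 FPKM, against 22.2 ± 2.76 in control. Also, 571 genes differed from control in the same direction as in HrasG12V, and 79 went the opposite way. Simulated control libraries gave at most 3 in the same direction, but genes were drawn independently there, so shifts of a whole library are not covered. The 571 changed widely when 1 library was left out. They became 245 without a filter, 286 at a mean of at least 5 FPKM, 283 with a replicate block and 296 with only the 2 groups compared. The labels name no batch, and a test of an unlabelled handling batch of control and Ctnnb1-depleted libraries was void, because 0 groups had libraries on both sides of the split. Eef1a1 lacked a value in the control and Ctnnb1-depleted libraries alone, along this split. Krt1 and Krt10 lacked one in the Mllt6-depleted libraries alone, which does not follow the split. The depletion itself, the biological explanation that the design gives, stays open and was not tested apart from the groups.

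The mean of Y-linked genes was at most 0.0123 FPKM in both Mllt6-depleted libraries and between 5.47 and 18 in the 6 others. Pools of female embryos only are a candidate explanation, since Xist was at 56.27 FPKM in the lower of these libraries and at 44.12 in the highest other one. Whether sex is also the source of the other called genes was tested between the control libraries and between the Ctnnb1-depleted libraries, which differ in Xist. Of 164 called genes, 63 (38.4%) differed in both pairs in the direction of the Mllt6 depletion, where chance gives 25% and 75% had been set for sex as the source. The share over all tested genes was 22.9%. Over the called genes, the change with Mllt6 depleted and the mean difference of the pairs had a correlation of 0.605 (slope 0.166). Both libraries of each pair held Y-linked reads, so the pairs are a weaker contrast of sex than the Mllt6 depletion. Sex of the pooled embryos cannot be told apart from Mllt6 depletion for the called genes, because both depleted pools lack Y-linked reads and the share of 38.4% lay between both bounds.

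Lce and other cornified envelope genes were lower with Mllt6 depleted. Reads split between near-identical Lce copies are argued against, because the sum over 17 Lce loci was 15.1% of its HrasG12V mean, with 139.9 and 61.1 FPKM against 600.7 and 727.7. Fewer granular cells in the sorted pools stay open, since the 14 other granular genes had a median log2 change of -0.92, with 3 lower and 0 higher at the limma threshold, against -2.65 (SD 0.69) over 15 Lce genes. A lower share of such cells and lower expression per cell cannot be told apart in sorted pools. The library with more Xist had the lower Lce sum in the control pair (174.4 against 445.7 FPKM) and the Ctnnb1-depleted pair (259.2 against 436.3) and the higher one in the HrasG12V pair (727.7 against 600.7), so the sex of the pools stays open here as well.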
